A study of Caenorhabditis elegans with 4 samples.

How the data were processed

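The series holds ChIP-seq of CBP-1 from mixed-stage N2 embryos kept at 20 °C, per the labels. Per the labels' protocols, embryos were fixed in 2% formaldehyde for 30 minutes, chromatin was sheared by sonication, 2 mg of extract entered each immunoprecipitation and 10% was kept as input. Libraries were made with single-end adaptors that carry an index. Samples were grouped by their titles into 2 CBP-1 ChIP samples and 2 inputs. Peak lists of both ChIP samples and 1 series-wide list were analysed. The inputs were not analysed here, so no background was measured the same way in control samples.

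Each list gives the first and last base of every peak and a score. The deposited score is the authors' own peak score, whose scale is not given in the sources used here. Per the file headers, the coordinates are in WormBase WS220. Per the submitters' processing notes, BWA and the build ce10 were used; the notes give no version. The caller is named MACS in both replicate lists and MACS v2 in the series-wide list, per the source column of the files. The call threshold, the control used, and whether the series-wide list came from pooled reads are not given in the sources used here. Because the callers differ, widths and scores of the series-wide list cannot be set against those of the replicate lists as measurements of binding. In the replicate lists the lowest scores on the nuclear chromosomes were 50.01 and 50.05, and 17 and 6 peaks shared the score 3100, so the order among those peaks is unresolved. The series-wide scores ran from 1.33 to 244.1. No list holds read counts, so depth is unknown, and the intervals given cover counting of peaks only.

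Mitochondrial peaks were left out of the comparisons. Chromosome lengths were taken as the furthest peak end on each chromosome over the 3 lists. The right end of each chromosome therefore holds a peak by definition in the list with the furthest peak. A peak was placed by its midpoint. Peaks counted as shared when they overlapped by at least 1 bp. Chance overlap came from 10000 circular shifts of the other list along each chromosome, which keep widths and spacing. Scores of shared and unshared peaks were compared with 100000 permutations. Densities on X against autosomes and in autosome centres against arms were tested with the exact two-sided binomial test against the share of length, and differences between shares with Fisher's exact test, adjusted by the Benjamini-Hochberg method over 10 tests. Intervals are 95% Wilson intervals for shares, exact Clopper-Pearson for the density ratios and exact Poisson for densities. Peaks lie closer together than independent draws would, so tests on single peaks give p-values that are too small. Permutation of whole 1 Mb bins, 100000 draws, was added for that reason after the data were seen.

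The comparisons, the alternatives, and the rule for named peaks were fixed before the data were examined. The rule takes the 10 series-wide peaks of highest score among those overlapped in both replicate lists. The alternatives were a reciprocal overlap of 50%, midpoints within 500 bp, the peaks above the median score of each list, equal list lengths, base pairs covered, another boundary between centres and arms, only peaks in both replicates, and each replicate list alone. Shifts of 10 to 100 kb and the removal of peaks wider than 2000 bp or within 1000 bp of a chromosome end were added later. Planned comparisons of peaks with promoters, transcript starts, 24 gene lists and 14 sequence motifs were not run, because they need a genome and annotation of WS220 and the gene table at hand is of assembly WBcel235. Coordinates were not converted between builds.

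The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The procedures were tested on simulated data. In lists of the replicate 1 size with 50.0% of peaks planted in both, 50.6% were recovered as shared. With an X ratio of 1.5 planted in 6289 peaks, the mean recovered ratio was 1.50, and 95% of the intervals held the planted value. The simulated peaks were placed independently, without the clustering of the real peaks. These checks therefore cover the computation, and do not show that the intervals hold for clustered peaks.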

Results

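The series mapped where CBP-1 sits on the genome of Caenorhabditis elegans embryos. CBP-1 is the worm member of the CBP/p300 family of histone acetyltransferases, co-activators that are found at promoters and enhancers in animals. Chromatin from mixed-stage embryos of the wild-type N2 strain was immunoprecipitated with a rabbit polyclonal antibody raised against CBP-1 and sequenced (ChIP-seq). There were 2 CBP-1 ChIP samples and 2 input samples. The 2 ChIP samples each had a list of peaks (regions called as enriched), and a series-wide list belonged to no single sample. The inputs were not analysed here. The labels do not say whether the ChIP replicates came from separate cultures, so differences between the lists may be technical as well as biological. Positions are in WormBase WS220. No gene annotation of that build was used, so peaks are described by chromosome and position, without gene names.

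The peaks were narrow and took up a small part of the genome in every list. The replicate 1 list held 3122 peaks, the replicate 2 list 2004 and the series-wide list 6300, of which 3121, 1994 and 6289 lay on the 6 nuclear chromosomes. Nuclear peaks had a median width of 427 bp in replicate 1, 159 bp in replicate 2 and 259 bp in the series-wide list. They covered 1.65 Mb in replicate 1, 0.504 Mb in replicate 2 and 2.13 Mb in the series-wide list. The last of these was 2.12% of the 100.3 Mb spanned by the nuclear peaks. The lists hold no read counts, so the sequencing depth behind each peak is unknown. Each peak's score is the authors' own, on a scale that is not known, and was used to rank and describe peaks within its list.

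The first comparison asked how far the replicates found the same sites. Most replicate 2 peaks were also present in replicate 1: 1590 of 1994, or 79.7% (Wilson 95% interval 77.9 to 81.4), overlapped a replicate 1 peak by at least 1 bp. In the other direction 1372 of 3121 replicate 1 peaks, or 43.96% (42.2 to 45.7), overlapped a replicate 2 peak. Sliding one list along each chromosome gave mean overlaps of 2.44% and 1.46%, so the observed overlaps were 32.7 and 30.1 times those of chance placement. None of 10000 shifts reached them (one-sided permutation p = 0.0001 for both, the smallest the shifts can give). The lists agreed far less on peak edges. When each peak of a pair had to cover at least 50% of the other, 21.4% of replicate 2 peaks and 13.7% of replicate 1 peaks counted as shared. That rule by its construction fails pairs of unlike width, and median widths were 159 bp in replicate 2 and 427 bp in replicate 1. With midpoints within 500 bp instead, 76.5% of replicate 2 peaks and 44.1% of replicate 1 peaks counted as shared. Of the bases that replicate 2 peaks covered, 88.7% lay inside replicate 1 peaks, while 27.1% of the replicate 1 bases lay inside replicate 2 peaks.

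Stronger sites were found in the other replicate more often than weaker ones. Each list was ranked by score and divided into 5 classes of equal size. In replicate 2, 99.5% of the strongest class were present in replicate 1 (98.2 to 99.9), against 60.3% of the weakest class (55.4 to 65.0). In replicate 1 the same shares in replicate 2 were 88.2% (85.4 to 90.5) and 14.6% (12.0 to 17.6). Shared peaks had a mean score of 502 in replicate 1 against 143 for unshared peaks, and 195 against 68.1 in replicate 2 (two-sided permutation p = 1e-05 for both, the smallest that 100000 permutations can give). The difference of 126.6 in replicate 2 was 253.9 when peaks had to cover each other reciprocally, and 53.4 without peaks wider than 2000 bp or within 1000 bp of a chromosome end. Shared peaks were also wider, with medians of 500 bp against 372 bp in replicate 1 and 183 bp against 111.5 bp in replicate 2. A wider peak is more easily overlapped by 1 bp, and the classes were not matched for width. Across the 1372 shared replicate 1 peaks, the rank by score in one replicate rose with that in the other (Spearman's rho 0.625, permutation p = 0.0001), a relation across peaks, which are not independent replicates. Each replicate 1 peak was paired with the highest score among the replicate 2 peaks that overlapped it. The pairs were not matched 1 to 1.

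**Figure D1:**
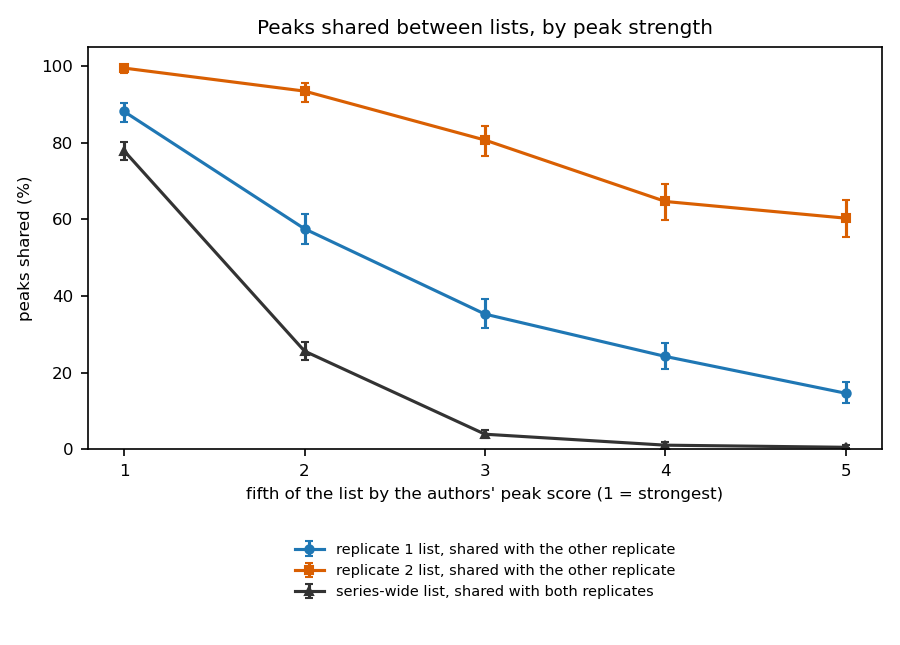
Share of peaks (%, vertical axis) found in the other list or lists, in 5 equal classes of the authors' score (horizontal axis, class 1 the strongest), with points for the shares and bars for Wilson 95% intervals. The share fell from 99.5% to 60.3% in replicate 2, from 88.2% to 14.6% in replicate 1 and from 77.9% to 0.477% for series-wide peaks present in both replicates.

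The second comparison set the series-wide list against the replicate lists. The series-wide list took in nearly all replicate sites: 99.1% of replicate 1 peaks (98.7 to 99.4) and 93.3% of replicate 2 peaks (92.1 to 94.3) overlapped it. The series holds no ChIP samples beyond the 2 replicates, so this overlap is not independent agreement. The series-wide list also held many peaks that neither replicate list had. Of its 6289 nuclear peaks, 1370 or 21.8% (20.8 to 22.8) overlapped both replicate lists, 33.1% (31.9 to 34.2) overlapped 1 of them and 45.2% (43.9 to 46.4) overlapped neither. With reciprocal cover 9.40% were in both, and among the series-wide peaks that scored above the list's median 42.4%. Peaks found in both replicates had a median score of 32.8 and a median width of 409.5 bp. Those in neither had a median score of 5.36 and a median width of 198 bp. Of the strongest of the 5 classes, 99.6% (99.1 to 99.8) were present in at least 1 replicate list, against 12.0% of the weakest (10.3 to 13.9). The 133 replicate 2 peaks that the series-wide list lacked were short, with a median width of 108 bp, and 5 of them were present in replicate 1.

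The 10 strongest series-wide peaks that both replicates shared lay on 5 of the 6 chromosomes, 4 of them on chromosome III and none on chromosome I. The strongest, with a score of 244.1, covered positions 11757170 to 11761325 of chromosome II, where both replicates had a peak at the score of 3100 that 17 replicate 1 peaks and 6 replicate 2 peaks carried. The next 2 lay on chromosome III, at 10758933 to 10759439 (score 231.9) and at 3867122 to 3867760 (score 231.1). A pair of neighbouring peaks on chromosome V, 9087371 to 9088774 (score 223.1) and 9088820 to 9090440 (score 222.2), were 45 bp apart. A second peak on chromosome II, 14404613 to 14405868, had a score of 210.3. A further pair of peaks, on chromosome III, covered 9053218 to 9054316 (score 207.7) and 7854372 to 7854802 (score 202.5). The last pair were a chromosome IV peak at 17277483 to 17279191 (score 202.2) and a chromosome X peak at 11605258 to 11606611 (score 201.7). These 10 peaks all stood among the strongest 53 peaks of replicate 1 and the strongest 87 of replicate 2. They may be fewer separate regions, since the pair on chromosome V lay closer than the 1 kb under which peaks were later merged.

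The third comparison concerned the chromosomes. Chromosomes I and III were the most densely occupied, with 75.6 (exact Poisson 95% interval 71.3 to 80.2) and 73.5 (69.0 to 78.2) series-wide peaks per Mb. Chromosome I was the denser of the pair in replicate 1 (38.1 against 36.9 per Mb), and chromosome III in replicate 2 (26.4 against 23.95) and among peaks in both replicates (17.6 against 16.9). Chromosome V was the least occupied, with 46.1 (43.3 to 49.1), and it was also the lowest in replicate 1 (21.1 per Mb) and replicate 2 (14.6 per Mb). Chromosomes II and IV had 62.4 and 57.9 peaks per Mb. Chromosome X, the sex chromosome, had 68.0 (64.2 to 71.9), within the range of the autosomes.

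The density of peaks on X exceeded the autosomal mean by a small factor in the series-wide list, and the replicates did not share this. The ratio of X to autosome density was 1.10 (95% interval 1.04 to 1.17, exact two-sided binomial p = 0.00235) in the series-wide list and 1.10 (1.01 to 1.21, p = 0.0347) in replicate 1. By the same exact test it was 0.927 in replicate 2 (0.822 to 1.04, p = 0.218), and 0.995 among series-wide peaks found in both replicates (0.862 to 1.14, p = 0.972). X held 19.1% of replicate 1 peaks and 16.6% of replicate 2 peaks (Fisher's exact test, p = 0.0232, adjusted p = 0.0332 over 10 tests). Single peaks are not independent, and the replicate lists share many sites. With whole 1 Mb bins as the unit, X averaged 68.1 ± 9.18 peaks (SD, 17 bins) and the autosomes 61.6 ± 20.4 (SD, 80 bins), a difference that did not pass the threshold (permutation p = 0.20, two-sided). Nor did that in replicate 1, with 33.9 ± 5.58 and 30.7 ± 11.6 peaks (SD, the same bins; permutation p = 0.26).

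Autosome centres carried more peaks than autosome arms. The centre was taken as the middle 33.3% of each chromosome, and the arms as the rest. In the series-wide list the 5 autosomes had 73.1 peaks per Mb in their centres and 55.9 in their arms, a ratio of 1.31 (1.24 to 1.38, exact binomial p = 1.94e-20). The centre was denser on all 5 autosomes, from 1.11 on chromosome IV (p = 0.110) to 1.61 on chromosome V (p = 4.60e-13, exact binomial tests). With 1 Mb bins as the unit, centres averaged 72.7 ± 16.8 peaks (SD, 27 bins) and arms 55.9 ± 19.9 (SD, 53 bins; permutation p = 4e-05). Neighbouring bins often held similar counts and each centre is a single stretch, so this p-value may still be too small. Peaks found in both replicates had a ratio of 1.23 (1.09 to 1.39, exact p = 0.000813). Replicate 1 alone gave 1.37 (1.27 to 1.49). Replicate 2 alone gave 1.05 (0.949 to 1.16, exact p = 0.336), with a denser centre on 3 of 5 autosomes, so that list by itself did not show the difference.

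**Figure D2:**
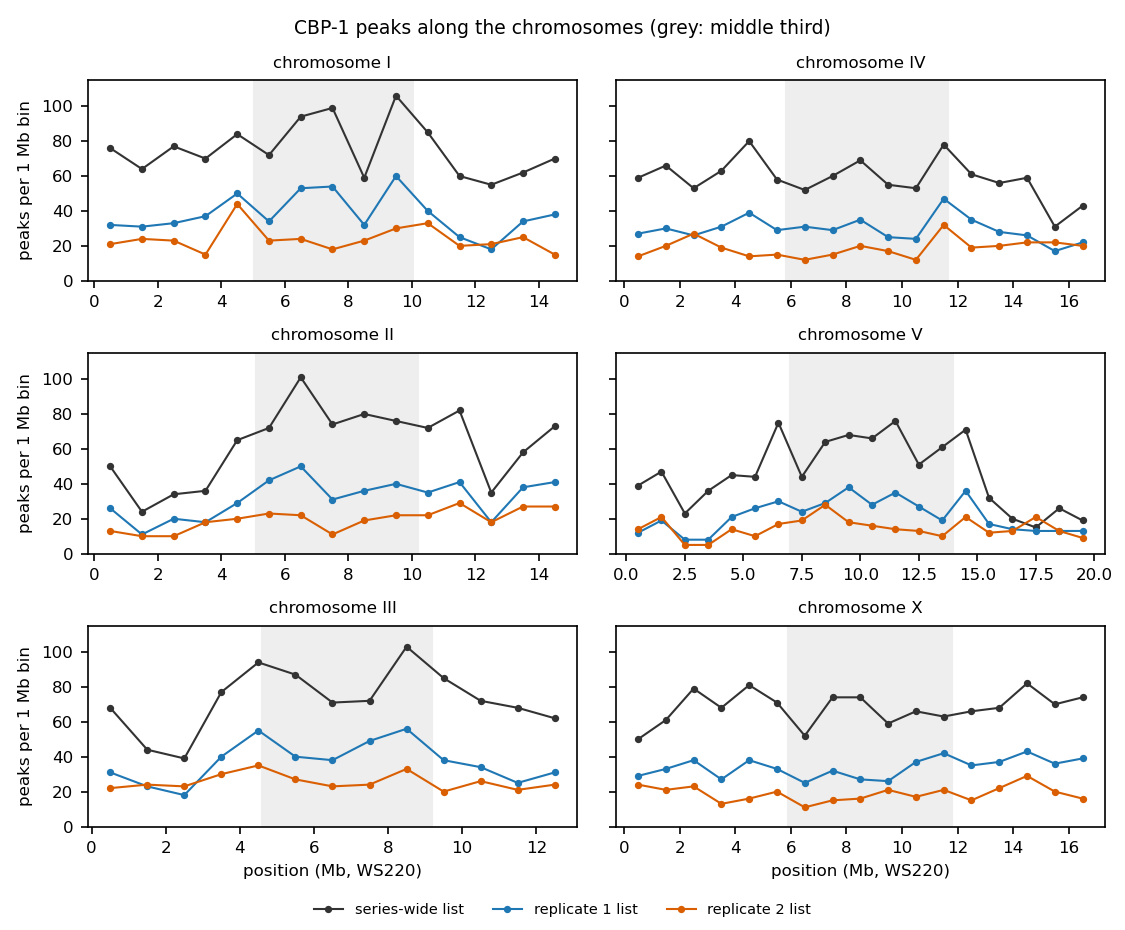
Peaks per full 1 Mb bin (vertical axis) against position in Mb of WS220 (horizontal axis) for each nuclear chromosome, with 1 line per peak list and the middle 33.3% of the chromosome in grey. Series-wide counts ran from 15 to 106 peaks per bin, with the densest bin on chromosome I and the sparsest on the right arm of chromosome V.

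The replicate lists differed in their share of peaks in autosome centres. Autosome centres held 40.7% of autosomal peaks in replicate 1 and 34.5% in replicate 2 (Fisher's exact test, adjusted p = 0.000148). That test takes the lists as independent sets, yet most replicate 2 peaks overlap replicate 1 peaks. All tests in this paragraph count single peaks, and none was repeated on bins, so their p-values overstate the evidence. Shared peaks overlap one another, so their shares in the centres are bound to be close: 430 of 1133 in replicate 1 and 496 of 1324 (37.5%) in replicate 2. Of the autosomal peaks absent from the other replicate, 42.9% in replicate 1 (597 of 1391) and 22.7% in replicate 2 (77 of 339) lay in the centres. Both differed from the shared peaks of the same list (Fisher's exact test, adjusted p = 0.0232 and 1.94e-06). Those replicate 2 peaks were also narrow, with a median width over all nuclear chromosomes of 111.5 bp against 183 bp for shared ones.

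Chromosome X had no such gradient. Its centre carried 65.5 series-wide peaks per Mb and its arms 69.2, a ratio of 0.947 (0.837 to 1.07, exact p = 0.392). The share of peaks in the centre was lower on X than on the autosomes in the series-wide list (32.1% against 39.5%, Fisher's exact test, adjusted p = 8.44e-06), in replicate 1 (31.8% against 40.7%, adjusted p = 0.000148) and among peaks found in both replicates (29.9% against 38.1%, adjusted p = 0.0305). In replicate 2 the shares were 30.5% and 34.5% (Fisher's exact test, adjusted p = 0.202). These tests count single peaks and none was repeated on 1 Mb bins, so their p-values overstate the evidence. The lists share many sites and are not separate evidence. The series-wide centre was denser with exact binomial p under 0.05 on 4 autosomes. On chromosome IV the ratio was 1.11 (exact p = 0.110), and 1.03 among peaks found in both replicates (exact p = 0.888). X was therefore not clearly set apart from chromosome IV.

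**Figure D3:**
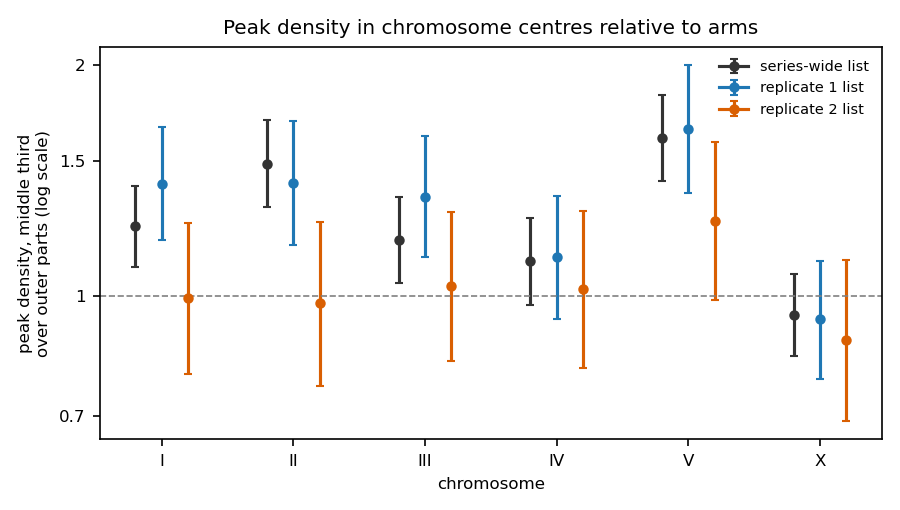
Peak density in the middle 33.3% of each chromosome divided by that in the rest (vertical axis, log scale), for the chromosomes on the horizontal axis and the 3 peak lists. Points are ratios, bars exact 95% binomial intervals and the dashed line equal density; the series-wide points lie above 1 on the 5 autosomes and at 0.947 on X.

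The densest 1 Mb bins were on chromosomes I, II and III. Positions 9000001 to 10000000 of chromosome I held 106 series-wide peaks, 60 replicate 1 peaks and 30 replicate 2 peaks. Positions 8000001 to 9000000 of chromosome III held 103, 56 and 33. At the other extreme, positions 17000001 to 18000000 of chromosome V held 15, 13 and 21. Much of the higher count in replicate 2 came from a single run, 17115349 to 17132151 in the series-wide list, which that list held as 4 peaks covering 12791 bp and replicate 2 as 9 peaks covering 12139 bp. These bins were chosen after their values were seen. Over the 97 full bins the replicate counts rose together (Pearson's r 0.629, Spearman's rho 0.559, permutation p = 0.0001 for both), and r was 0.596 without the 2 bins farthest from the replicate 1 median. Bins of 1 genome are not independent samples.

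A few broad regions stood out against the narrow majority. Only 43 series-wide peaks were wider than 2000 bp, with a median score of 36.9 against 8.74 for the others. Of the wide peaks, 35 were present in both replicates, a share that cannot be compared fairly with that of narrower peaks, because a wider peak is more easily overlapped by 1 bp. The broad regions described here were chosen after their values were seen. The widest, 11201 bp, covered 15060196 to 15071396 near the right end of chromosome I, and both replicates had a peak there at a score of 3100. The second spanned 8206 bp of chromosome V, from 7916835 to 7925040. The third covered 17119884 to 17126645 of chromosome V, within the run described above, which replicate 1 also held as 4 peaks. In C. elegans the tandem genes of the large and small ribosomal RNAs lie at the right end of chromosome I and those of the smallest ribosomal RNA on the right arm of chromosome V. Whether the broad peaks cover those genes was not tested here.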

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

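Peaks on the mitochondrial genome were outside every comparison, and each list held some. The series-wide list had 11 mitochondrial peaks covering 7007 bp. Replicate 1 had 1, of 2543 bp and a score of 123.8. Replicate 2 had 10, covering 10350 bp from position 4 to position 12750, with a highest score of 314.7. Replicate 2, the shorter list, thus held more mitochondrial peaks than replicate 1, the reverse of every nuclear chromosome. No test was run on these peaks. The input level on the mitochondrial genome was not analysed here, so it is not known whether these peaks exceed it.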

How the results depend on the processing

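Local shifts, the removal of wide and chromosome-end peaks, and the permutation of 1 Mb bins were tests chosen after the data were seen; the others were planned. The overlap of the replicates stayed above chance under all 6 alternatives in each direction, from 13.7% to 58.2% for replicate 1 and from 21.4% to 82.0% for replicate 2. The higher score of shared peaks held under both alternatives tried. The makeup of the series-wide list moved with the setting. With reciprocal overlap of 50%, 9.40% of its peaks were in both replicate lists, 39.6% in 1 and 51.04% in neither. Above its median score, 42.4% were in both, 46.1% in 1 and 11.5% in neither. The ratio of X to autosome density lost its call above the median score (1.04, exact p = 0.362) and with 1 Mb bins permuted (1.11, permutation p = 0.20). Among peaks in both replicates the densities were nearly equal (0.995, exact p = 0.972). Over the single replicate lists the ratio ran from 0.927 without replicate 1 to 1.10 without replicate 2. The value without replicate 1 did not differ clearly from equal density (exact p = 0.218). The ratio of autosome centres to arms kept its direction under all 7 alternatives and lost its call without replicate 1 only. Its values ran from 1.05 to 1.44, the highest with a wider centre, and over the single replicate lists from 1.05 without replicate 1 to 1.37 without replicate 2. The cause of these changes was not tested, but the reciprocal rule by its construction counts fewer pairs of peaks of unlike width. Comparisons with promoter windows, transcript starts, gene lists and motifs, and their other settings, were not run, for want of a WS220 annotation here. No paired analysis was possible because the inputs were not analysed here. The lists hold no depth, so a site missing from a list cannot be called unbound. Leaving out a replicate gives no value for the overlap of the replicates.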

Other observations

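The test of random placement at the left chromosome ends and that of repeat copies were chosen after the result was seen; the others were written down before their results. All 6 left chromosome ends had a series-wide peak within their first 1000 bp, and both replicates had one there too, with highest scores from 255.6 on chromosome III to 1158 on chromosome I in replicate 1 and from 209.8 to 896.2 in replicate 2. The right ends are left out of the test. Each was set at the last base of the furthest peak, always a series-wide one, so that list holds a peak there by definition. Within 1000 bp of that base, replicate 1 had a peak at 1 right end and replicate 2 at 2, against 6 left ends in each.

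Random placement of the series-wide peaks covered 0.369 left ends on average and at most 4 in 10000 draws (one-sided p by permutation of peak positions 0.0001, the smallest the draws can give), which argues against chance as the source of peaks at the left ends. A candidate explanation is reads from many copies of a repeat placed on the outermost bases, since worm chromosomes end in telomere repeats. The 6 left ends with a peak in both replicates go with it, but binding at the ends would give the same. Only 1 right end had a peak in both replicates, and neither explanation by itself says why the sides differ in the replicate lists. The replicate peaks at that end, on chromosome IV, stopped at 17492982 and 17492922, short of the last base, 17493824. Highest series-wide scores ran from 14.6 to 76.1 at the right ends and from 15.3 to 90.4 at the left ends. The chromosome I right-end peak, with the score of 76.1, overlapped no peak of either replicate. The input libraries that would tell the explanations apart were not analysed here. No biological explanation was tested for any of these patterns.

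Peaks lay close to one another. In the series-wide list 60.3% of peaks (Wilson 95% interval 59.1 to 61.5) had another within 5 kb, against 48.5% on average when peaks were placed at random within their own 1 Mb stretch (one-sided p by permutation of positions 0.001, the smallest that 1000 draws can give). Uneven density on the scale of 1 Mb is therefore not the whole of it. Nor is the splitting of broad regions by the caller over gaps under 1 kb. After such peaks were merged, 44.9% had a neighbour against 33.3% in the same random placement (p by permutation 0.001). In replicate 1 it was 28.1% against 18.8%, and in replicate 2 303 of 1680 merged regions against 12.5%. Clustering of genes or of regulatory sites may remain as an explanation and was not tested, for want of an annotation of this build.

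The share of peaks on X was higher in replicate 1 (19.1%) than in replicate 2 (16.6%). Wide and chromosome-end peaks are unlikely to be the whole reason, since without them the shares were 19.1% and 16.5% (Fisher's exact test, p = 0.0221). The length of the replicate 1 list could contribute. Its strongest 1994 peaks, as many as replicate 2 has, had 18.5% on X (exact interval 16.8 to 20.3), against an interval of 15.0 to 18.3 in replicate 2, a difference that no longer passed the test (p = 0.123). The rule written beforehand counted a share above the replicate 2 interval against list length. That share lies above it by less than its own spread, which the rule did not consider. The cut to equal length therefore does not tell list length apart from other differences between these libraries. The classes of replicate 1 go with list length, but no test was run across them. These tests also treat the lists as independent sets of peaks, though the lists share many sites.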
